A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

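Budding yeast (Saccharomyces cerevisiae) cells were sampled by filtration during meiosis, and poly(A)+ RNA was isolated from each sample, per the labels' protocols. Complementary DNA of each time point carried the red dye and competed on a 2-colour microarray with a common mix of meiotic messenger RNA in the green dye, per the labels and the series design. The deposited value of a gene is the log2 of its ratio to the mix at that time point divided by its ratio to the mix at 0 h, as the authors describe it in the series design. A value of 0 is therefore the level at 0 h, and a positive value is a higher level than at 0 h. The design text names 3 independent cultures, and the deposited table has 1 column for each of the 7 time points (1, 2, 3, 4, 5, 6 and 8 h). How the cultures were combined, the background correction, the normalization within arrays, the filters, the array platform and the strain are not given in the sources used here.

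The authors' log2 table was used as deposited, with no further normalization. Its column medians were 0.01, -0.01, -0.01, 0.00, -0.02, -0.03 and -0.04 from 1 h to 8 h. Whether each column was centred by the authors is unknown, and so is any rescaling. The direction of the ratios follows the series design. Because every column was divided by the same 0 h ratio, an error in a gene's 0 h value enters all 7 of its values. The size of a very large ratio can depend on the background handling at 0 h, which is unknown. No spot intensities were used here, so signal over background could not be set beside a value, and the number of arrays limits the precision.

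The table has 6141 rows named by systematic gene names. Values at all 7 time points were present in 5666 rows, no value in 475, and a partial set in 0. No row name was duplicated. Rows were given standard names through the RefSeq table of the R64 assembly. Its positions were used only for the neighbouring pairs of induced genes. For the unannotated reading frames, neighbours were rows numbered next to each other in their systematic names, with suffixed names left out. Of all rows, 5655 matched it and 486 did not. Of the rows with values, 5223 matched a protein-coding gene, 15 a pseudogene and 428 no annotated gene, and 4774 had a standard name. Rows without a value made up 7.37% of the matched and 11.9% of the unmatched rows. All rows with values are called genes below.

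With 1 column per time point there is no replicate check and no p-value for a single time point. A gene was called induced when its log2 ratio was 1 or more at 2 or more consecutive sampled time points, and repressed when it was -1 or less at 2 or more consecutive time points. This is a fixed rule of size and not a test. Change within the course was tested with limma 3.58.1 in R 4.3.3, as a linear and a quadratic term of time fitted to the 7 log2 values of each gene, with a moderated F test of the 2 time coefficients and Benjamini-Hochberg adjustment at 0.05 over all 5666 genes. The fit leaves 4 residual degrees of freedom per gene, to which the moderation added 2.354. The direction of a called gene is the fitted value at 8 h minus that at 1 h. These p-values measure the scatter of the time points around a smooth curve and not the spread between cultures, and time points of the same cultures can share errors, which makes p-values too small. The division by 0 h falls in the intercept, which was not tested. A curve of this kind can overshoot genes that step up and miss sharp peaks, so measured log2 values are given below and not fitted changes.

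The trend test was tested on simulated data with 200 of 5666 genes given a linear change over the course. It recovered 22.1% of the 68 genes with a log2 change of 1, 74.2% of the 66 with a change of 2 and 87.9% of the 66 with a change of 3, and 1.6% of its calls were false. The simulated errors were independent between time points. These rates therefore need not hold for the real columns, which can share errors and hold steps and peaks.

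Genes were grouped by 26 fixed lists, and 8 further lists were chosen after the values were seen and are used only in the closing observations. For each list the median log2 ratio at each time point was set against 10000 random lists of the same size drawn from all 5666 genes, as a description of these columns. Members called by the trend test were counted over all genes and adjusted over the list alone. Genes named in the text are 20 landmark genes of meiosis, the 10 genes with the highest and the 10 with the lowest level held over 2 consecutive time points among genes with a standard name, and up to 2 highest and 2 lowest members of each fixed list by the same measure. The lists, the naming rule, the calling rule, the trend test and the alternatives in the closing section were set before the data were examined, except where the text says that something was chosen later. Genes named outside this rule, such as the members behind a small count, were chosen after their values were seen.

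Alternatives covered other scalings of the columns, fold thresholds of 1.5 and 3, runs of 1 and 3 time points, other curves and variance estimates in the trend test, the mean in place of the median of a list, and each time point left out. Correlations, random lists, bootstraps and shuffles were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.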

Results

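Messenger RNA levels in sporulating yeast cultures were followed at 7 time points from 1 h to 8 h, each as a log2 ratio to the level at 0 h. The series asks how transcript levels are regulated through meiosis, the pair of divisions that turns a diploid cell into haploid spores. Each time point is 1 deposited column, so no value below has a replicate error. An adjusted p given beside 2 hours belongs to the trend over all 7 time points and not to the step between those hours. Induced and repressed below mean at least 2-fold above or below 0 h at 2 or more consecutive time points, a rule of size, and rose, fell and changed refer to genes called by the trend test.

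Many transcripts differed from their 0 h level at every time point. Between consecutive time points from 1 h on, the largest number of genes differing by at least 2-fold was 605, from 4 h to 5 h. By Pearson correlation across genes, 1 h and 2 h were less alike (0.846) than 4 h and 5 h (0.862). The interval from 0 h to 1 h is outside this ranking. By the 1 h counts given below, more genes than 605 differed by at least 2-fold across it. Over the whole course 1236 genes were induced and 932 were repressed, and 11 genes met both rules at different times. With the ratio taken to 1 h in place of 0 h, a check chosen after the values were seen, 1109 genes were induced and 603 were repressed. Together 2157 genes (38.1%) met at least 1 of the rules. At 1 h, 403 genes stood at least 2-fold above 0 h and 582 at least 2-fold below it, and at 5 h the numbers were 996 and 870. The first run of induction began at 1 h for 329 genes and at 5 h for 406. Counts at a fixed 2-fold cut also grow when the ratios spread wider, as they did from 4 h to 5 h. Whether a common scale factor made part of the 5 h counts was not tested. The ratios of 811 induced genes (65.6%) were highest at 5, 6 or 8 h, 448 of them at 8 h (705 on the fitted quadratic curve). All 7 values were at least 2-fold above 0 h in 163 genes and at least 2-fold below it in 154.

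**Figure D1:**
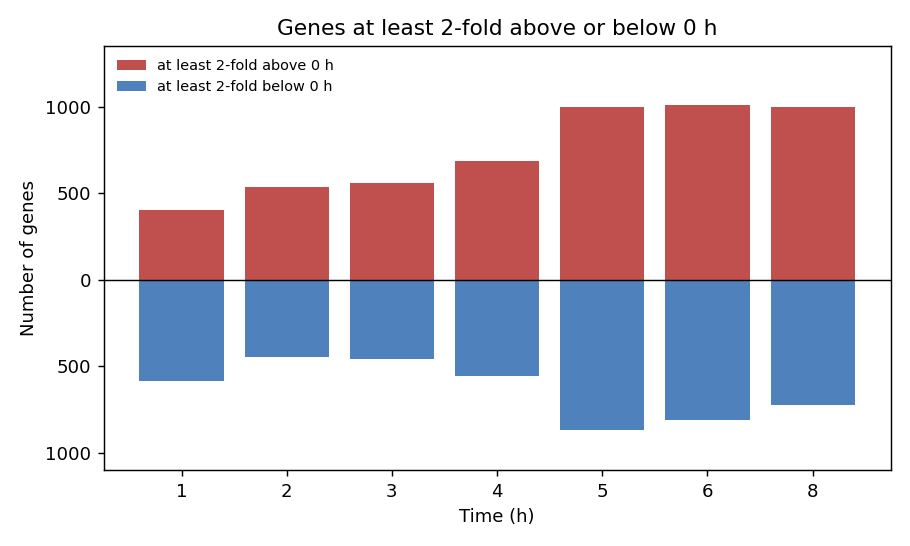
Number of genes at least 2-fold above 0 h (upward bars) or at least 2-fold below 0 h (downward bars) against time in hours, 1 deposited column per time point. The upward count was 688 at 4 h and 996 at 5 h, and the downward count was 553 at 4 h and 870 at 5 h. The cut is fixed, and the ratios spread wider at 5 h than at 4 h.

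The sporulation genes SPS2, SPS4, SPR2, SPS1 and SPR3 held the highest ratios, followed by the chitin deacetylase gene CDA1, the hexose transporter family member HXT14, and PES4, SPO74 and SPR28. SPS4 reached a log2 ratio of 11.75 and SPS2 reached 11.70 at 8 h, after values of -0.90 and 0.08 at 2 h. At the other end stood glycolytic genes, with the enolase genes ENO2 at -5.80 and ENO1 at -5.78 at 6 h, along with PGK1, GPM1, TDH1, TDH3 and TPI1. The gluconeogenic gene FBP1 (-5.42 at 5 h), the cell wall glycoprotein gene YGP1 (-5.10 at 5 h) and the pyrimidine synthesis gene URA1 (-4.87 at 5 h) completed the 10 lowest. The enolase pair and the TDH genes have near-identical copies, so the value of any single member is uncertain.

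Consecutive columns resembled each other, with Pearson correlations across genes of 0.846 between 1 h and 2 h, 0.937 between 2 h and 3 h, and 0.920 between 3 h and 4 h. The correlation was 0.862 between 4 h and 5 h, 0.991 between 5 h and 6 h and 0.970 between 6 h and 8 h. The numbers of genes differing by at least 2-fold between those neighbours were 335, 55, 120, 605, 9 and 96. The SD over genes was 0.907 at 3 h, 1.05 at 4 h and 1.48 at 5 h. Genes are not independent replicates, and all columns share the division by 0 h, which can raise or lower these correlations.

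The genes of chromosome axis and synapsis were already high at 1 h, and the medians of the axis, break formation and strand exchange lists were highest at 4 h. The early meiotic genes encode the switch into meiosis and the machinery that breaks, pairs and recombines homologous chromosomes. IME1, the master activator of entry into meiosis, stood at a log2 ratio of 2.22 at 1 h, was highest at 2 h (2.85) and ended at 1.31. IME2, the meiotic protein kinase, went from 4.38 at 1 h to 6.61 at 6 h. NDT80, the transcription factor of the middle genes, stood at -0.10 at 2 h, 1.62 at 3 h, 4.32 at 4 h and 6.90 at 5 h.

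Of 14 measured meiotic regulators 9 were induced, 0 were repressed and 5 met neither rule. The induced ones included the RNA-binding protein gene RIM4 (2.83 at 4 h) and the splicing factor gene MER1 (3.23 at 4 h), as well as HST1 and RFM1, partners of the repressor Sum1, at 2.45 and 2.21 at 6 h. SIN3, RIM11, RIM101, UME6 and SUM1 met neither rule, and SUM1 itself ranged from -0.15 to 0.49. Over all genes 9 of the 14 were called by the trend test, and 11 were called adjusted over the list alone.

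The genes for meiotic double-strand break formation had a median of 0.98 at 1 h and 2.89 at 4 h. SPO11, which encodes the protein that cuts the DNA, was highest at 4 h (4.98), as was REC102 (5.17). Among 9 measured members 7 were induced, while RAD50 (0.92 at 3 h) and XRS2 (0.34 at 1 h), which also serve repair in growing cells, met neither rule. The trend test called 8 of these 9 over all genes and 8 adjusted over the list alone.

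All 16 measured genes of the chromosome axis and synapsis were induced. Their median was 2.31 at 1 h and 4.35 at 4 h, above all 10000 random lists at each time point. REC8, the meiotic cohesin subunit, reached 6.60 at 3 h, the kinase gene MEK1 5.98 at 4 h, HOP1 5.48 at 4 h and ZIP1, of the central region of the synaptonemal complex, 4.70 at 4 h. The lowest held level in this list belonged to CST9, also known as ZIP3, whose highest single value was 2.04 at 4 h, and ZIP2 reached 3.20. By the trend test 15 of the 16 changed over all genes and 16 adjusted over the list alone, with MEK1 the exception over all genes (adjusted p = 0.0562).

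Most strand exchange genes were induced, to different heights. DMC1, the meiotic recombinase, stood at 5.23 at 1 h and 5.83 at 4 h, and its accessory factor gene MEI5 reached 5.70. RAD52, used in mitotic repair as well, reached 2.00 at 4 h. Of 10 measured members 8 were induced, and RAD55 (between -0.65 and 0.43) and RDH54 (between 0.58 and 0.75) met neither rule. Only 4 of the 10 were called by the trend test over all genes and 4 adjusted over the list alone (DMC1, MEI5, HOP2 and RAD52), and RAD57, induced at up to 1.42, was not among them (adjusted p = 0.111).

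**Figure D2:**
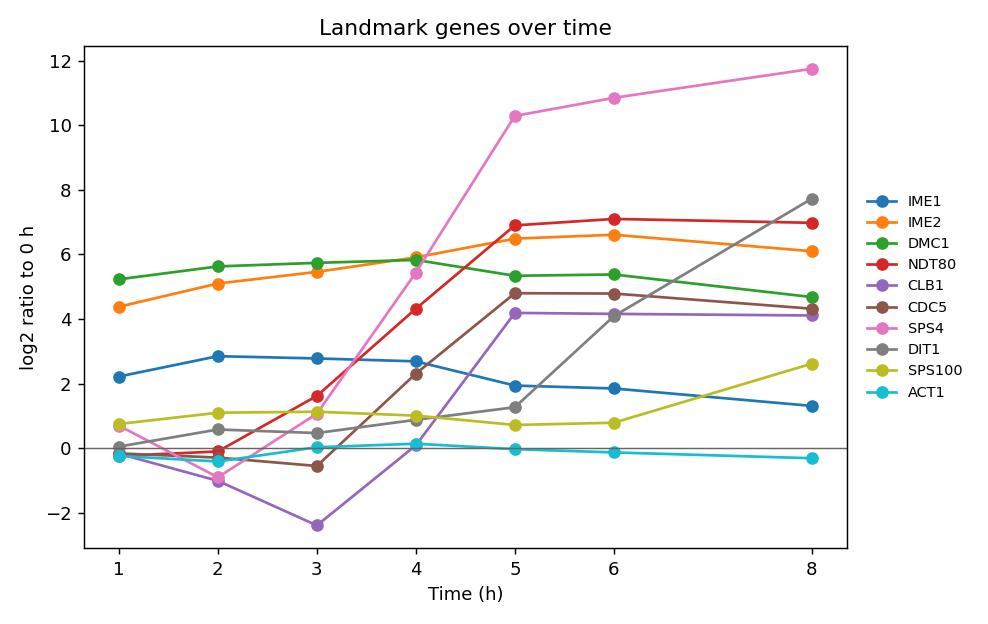
Log2 ratio to 0 h against time in hours for 10 landmark genes, 1 deposited value per point and no error bars because each time point is 1 column. DMC1 stood at 5.23 already at 1 h, NDT80 at 1.62 at 3 h, and DIT1 at 1.27 at 5 h and 7.73 at 8 h, while ACT1 stayed between -0.41 and 0.14.

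Genes of the premeiotic DNA synthesis phase were highest at 2 h. The median of 24 measured DNA replication genes was 0.83 at 1 h, 1.22 at 2 h and 0.16 at 8 h. It stood above 98.5% of random lists at 5 h and above 97.2% at 6 h. RNR1, the large subunit of ribonucleotide reductase, was highest at 2 h (1.50) and fell to -0.61 at 8 h (adjusted p = 0.0414), with a scatter around the curve of 0.438. MCM7, of the replicative helicase, fell from 0.85 at 1 h to -0.85 at 8 h (adjusted p = 0.0043). The S-phase cyclin genes CLB5 and CLB6 behaved differently from the rest of the list, at 2.47 and 1.71 at 2 h and 4.34 and 5.65 at 5 h. Of the 24, 10 were induced and 14 met neither rule, among them CDC6 at -0.64 to -0.09. Changes with time were called for 15 of the 24 over all genes and for 15 adjusted over the list alone, 13 of them downward.

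The core histone list also holds the linker histone gene HHO1 and the variant gene HTZ1, and all 10 of its genes were induced. Their median was -0.005 at 1 h, 2.05 at 2 h, 1.88 at 3 h and 1.04 at 4 h. HTA2 stood at 2.71 at 2 h and HHT2 at 1.74. HHO1 and HTZ1 took another course, rising to 2.49 (adjusted p = 0.0158) and 1.19 (adjusted p = 0.00984) at 8 h. Those were the 2 histone genes that the trend test called over all genes, and the same count of 2 was found adjusted over the list alone. The gene pairs of each core histone are near-identical copies, so their separate values are uncertain.

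Cohesin genes, whose product holds sister chromatids together, had a median of 1.65 at 2 h and 0.22 at 8 h. REC8, counted here as well as in the axis list, was the highest, and PDS5 stood at 2.65 at 2 h (adjusted p of its trend 0.0507). MCD1, the mitotic counterpart of REC8, fell from 0.32 at 1 h to -1.34 at 8 h (adjusted p = 0.00628). Of 10 members 7 were induced, MCD1 alone was repressed, and SCC4 and RAD61 met neither rule. For this list the trend test called 7 over all genes and 8 adjusted over the list alone.

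The medians of the middle, meiotic division and late lists stayed below a log2 ratio of 1 up to 3 h and then stepped up between 3 h and 5 h. The division median was already 0.57 at 2 h and the late median 0.95 at 3 h. All 27 middle sporulation genes were induced. Their median was 0.09 at 2 h, 0.59 at 3 h, 3.27 at 4 h, 6.48 at 5 h and 7.26 at 8 h. SMK1, a kinase of spore wall assembly, rose from 0.59 at 3 h to 4.68 at 5 h (adjusted p = 0.0153), and SPS1, another kinase of spore formation, from 0.31 to 8.75 (adjusted p = 0.00923). SSP1, which acts at the edge of the growing spore membrane, stood at 8.26 at 6 h and GIP1, a phosphatase subunit, at 5.17 at 8 h. Among the 27, 26 rose over all genes and 27 adjusted over the list alone, the exception over all genes being SPO73 (2.52 at 5 h, adjusted p = 0.0536).

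The median of 14 measured genes of the meiotic divisions was 1.87 at 4 h, 3.95 at 5 h and 3.99 at 6 h. CDC5, the polo kinase, rose from -0.55 at 3 h to 4.79 at 6 h (adjusted p = 0.0254), and the B-type cyclin gene CLB3 from 0.62 to 3.81 (adjusted p = 0.0147). CLB1, another B-type cyclin gene, met both rules, with -2.39 at 3 h and 4.19 at 5 h, and its trend did not pass (adjusted p = 0.0664). CLB2, the main mitotic cyclin gene, ranged from -0.86 to 0.56 (adjusted p = 0.378), and together with the separase gene ESP1 met neither rule. MAM1, of the monopolin complex, reached 6.80 at 5 h, and AMA1, a meiotic activator of the anaphase-promoting complex that also belongs to the middle list, 7.54 at 8 h. AMA1 and SPO13, a regulator of the first division, were already induced at 1 h (2.56 and 3.60). In this list 12 were induced and 11 were called over all genes, against 12 adjusted over the list alone, all of them upward.

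The spore wall and late list reached its highest median at 8 h (6.89), after 0.95 at 3 h and 6.40 at 5 h. All 17 members were induced. Within it the time of the rise differed between genes. The chitosan layer gene CDA1 and DTR1, a dityrosine transporter gene, stood at 8.66 and 6.40 at 5 h, and SPR1, a glucanase gene, at 7.63. DIT1, which makes the dityrosine of the outer wall, stood at only 1.27 at 5 h and rose to 4.09 at 6 h and 7.73 at 8 h (adjusted p = 0.00249). SPS100, a late wall maturation gene, stood at 0.79 at 6 h and 2.62 at 8 h (adjusted p = 0.0482), after an early level of 1.13 at 3 h. Upward trends were called for 16 of the 17 over all genes and for 17 adjusted over the list alone, with SHC1 the exception (adjusted p = 0.0733).

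**Figure D3:**
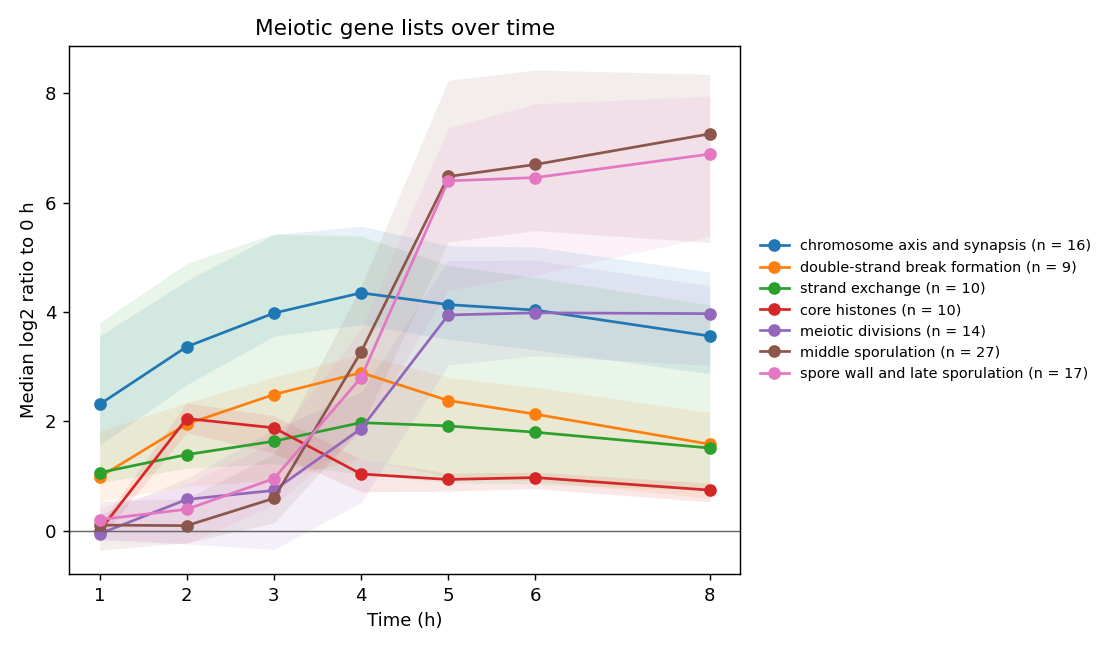
Median log2 ratio to 0 h of 7 fixed gene lists against time in hours, with a shaded band from the lower to the upper quartile of the members and n the number of measured members. The core histone list was highest at 2 h (2.05), the axis and synapsis list at 4 h (4.35), and the middle list stood at 0.59 at 3 h and 6.48 at 5 h.

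The order of the highest medians was 2 h for DNA replication, core histones and cohesin, 4 h for break formation, axis and synapsis, and strand exchange, 5 h for the meiotic regulators, 6 h for the divisions and 8 h for the middle and late lists. Medians at neighbouring hours were often close, as at 5, 6 and 8 h for the divisions (3.95, 3.99 and 3.97). With each column scaled to the same spread, the break formation and axis lists were highest at 3 h and the divisions at 8 h.

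Glycolysis was the most deeply lowered fixed list, and genes of the ribosome were lowest at the start of the course. The glycolysis median was -2.15 at 1 h and -4.60 at 6 h, below all 10000 random lists at each time point. Of its 16 genes 15 were repressed, with PFK1 the exception (-0.82 to -0.30, adjusted p = 0.867), whose partner subunit gene PFK2 fell from -0.40 to -2.05 (adjusted p = 0.0059). ENO1 fell from -2.74 at 1 h to -5.34 at 8 h (adjusted p = 0.00357) and TPI1 from -1.80 to -4.89 (adjusted p = 0.00277). Downward trends numbered 13 over all genes and 13 adjusted over the list alone.

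Among 128 measured cytosolic ribosomal protein genes 106 were repressed, 0 were induced and 22 met neither rule. The median was -2.29 at 1 h, -0.93 at 3 h, -1.70 at 5 h and -0.87 at 8 h, so the list had a low at 1 h and another at 5 h. RPL27A stood at -3.43 at 1 h and -1.35 at 3 h, and RPS2 at -2.72 and -1.75. RPL22A (0.18 at 3 h) and RPS9B (0.06 at 3 h) had the highest held levels, and neither passed the trend test. The trend test called 17 members over all genes and 1 (RPL19B, from -1.85 at 1 h to 0.73 at 8 h) adjusted over the list alone. Many of these genes are near-identical pairs whose separate values are uncertain.

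Ribosome biogenesis genes had a similar shape, with medians of -1.96 at 1 h, -0.55 at 3 h, -1.23 at 5 h and -0.32 at 8 h. NOP56 and CBF5, of the box C/D and H/ACA particles that modify ribosomal RNA, stood at -3.55 and -3.20 at 1 h and at -1.35 and -1.28 at 3 h. Of 20 measured members 10 were repressed and 10 met neither rule, among them NOP4 (-1.55 at 1 h, 0.25 at 2 h). Over all genes 3 were called by the trend test (MAK5, ERB1 and UTP4), and 0 adjusted over the list alone.

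Respiratory genes were lower than at 0 h throughout. The oxidative phosphorylation median was -1.19 at 1 h, -0.85 at 4 h and -1.73 at 8 h, below all random lists at each time point. COX12 of cytochrome oxidase fell from -1.33 to -2.90 (adjusted p = 0.00759), and ATP2 of the ATP synthase from -1.18 to -2.58 (adjusted p = 0.0165). COR1 ranged from -0.55 to -0.20 and CYT1 stood at -0.43 at 1 h and -1.36 at 8 h, and the trend of CYT1 did not pass (adjusted p = 0.0895). Of 24 genes 19 were repressed and 5 met neither rule (COX9, QCR6, QCR9, COR1 and ATP7), with 6 called by the trend test over all genes and 3 (COX12, COX13 and ATP2) adjusted over the list alone.

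The TCA cycle list stayed near 0, with medians from -0.27 to 0.19, and its members went both ways. SDH3 and SDH1, of succinate dehydrogenase, fell to -1.96 and -1.36 at 8 h (adjusted p = 0.00883 and 0.027), while LSC1 stood at 1.32 at 5 h (adjusted p = 0.288) and IDH1 at 1.08 at 4 h. Only LSC1 was induced, 5 of the 14 were repressed (SDH1, SDH3, KGD1, KGD2 and MDH1) and 8 met neither rule, and 8 changed over all genes against 9 adjusted over the list alone.

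Gluconeogenic and glyoxylate genes differed from each other as well. FBP1 was repressed from 1 h (-3.28) and fell further to -5.17 at 8 h (adjusted p = 0.00393), whereas PCK1 rose from -3.15 at 1 h to 0.38 at 8 h (adjusted p = 0.00277). The acetate transporter gene ADY2 was induced throughout (2.37 to 3.41), and ACS1, acetyl-CoA synthetase, fell from 1.98 to 0.04 (adjusted p = 0.0036). The list median was 0.98 at 1 h and -0.66 at 8 h, with 4 of 12 induced (ADY2, ACS1, CIT2 and CAT2), 5 repressed (FBP1, PCK1, MLS1, SFC1 and YAT1) and 3 in neither class (ICL1, MDH2 and YAT2). Trends were called for 10 over all genes and 12 adjusted over the list alone.

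**Figure D4:**
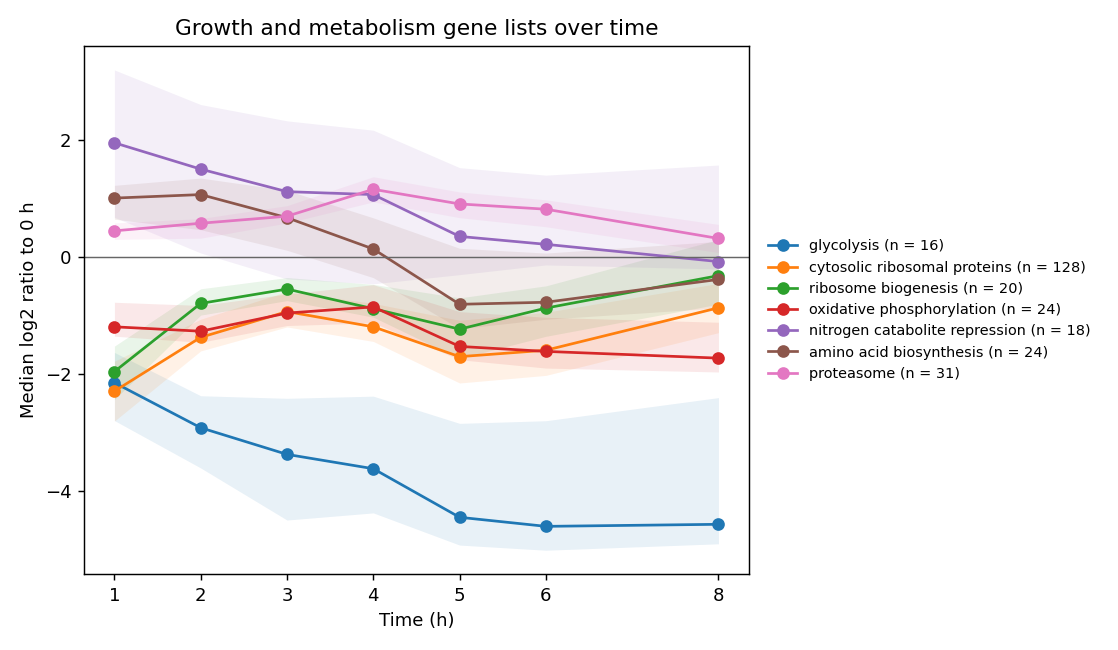
Median log2 ratio to 0 h of 7 fixed lists of growth and metabolism against time in hours, with a shaded band from the lower to the upper quartile of the members and n the number of measured members. Glycolysis stood at -2.15 at 1 h and -4.60 at 6 h, ribosomal protein genes at -2.29 at 1 h and -0.93 at 3 h, and nitrogen catabolite repression genes at 1.96 at 1 h and -0.08 at 8 h.

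Genes for the use of poor nitrogen sources were high at 1 h and fell afterwards. The median of 18 measured genes under nitrogen catabolite repression was 1.96 at 1 h, 1.07 at 4 h and -0.08 at 8 h. MEP2, the high-affinity ammonium permease, fell from 6.61 at 1 h to 1.70 at 8 h (adjusted p = 0.00355), and DAL5, the allantoate permease, from 5.30 to 2.16 (adjusted p = 0.00249). The proline genes PUT4 and PUT1 were repressed, with PUT4 at -2.09 at 1 h and -4.03 at 4 h and PUT1 falling from 0.87 to -1.89 (adjusted p = 0.00277). In total 12 were induced, 4 were repressed (also DAL7 and GDH2), and MEP3 and PUT2 met neither rule. Of the 18, 15 were called over all genes and 15 adjusted over the list alone, 14 of them downward and GLN1, glutamine synthetase, upward to 2.42 at 8 h.

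Amino acid biosynthesis genes had a median of 1.07 at 2 h, 0.14 at 4 h and -0.81 at 5 h. LEU1 was the highest, at 2.91 at 2 h (adjusted p of its trend 0.0878), and ARG4 fell from 2.57 at 1 h to 0.83 at 8 h (adjusted p = 0.00552). HIS4 fell from 0.50 to -2.29 (adjusted p = 0.0053). ARG1 was induced early (1.54 at 2 h) and repressed late (-1.66 at 8 h), and the gene of the ARG5,6 protein did the same. Of 24 members 11 were induced and 7 repressed, 2 of them in both classes, and 8 met neither rule. All 17 calls over all genes were downward, and 18 were called adjusted over the list alone.

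The proteasome list was highest at 4 h, with a median of 1.16, and returned to 0.32 at 8 h. RPN7 of the regulatory particle was at 0.55 at 1 h, 1.48 at 4 h and 0.59 at 8 h (adjusted p = 0.00568), a rise and return, and RPN8 reached 1.59 at 5 h. PRE7 and RPN9 had the lowest held levels and reached at most 0.64 and 0.45. Of 31 genes 13 were induced, 0 were repressed and 18 met neither rule, and 20 changed over all genes against 25 adjusted over the list alone.

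Autophagy genes had medians from 0.39 to 0.76. ATG8, whose product coats the autophagosome, rose from 1.92 at 1 h to 4.24 at 8 h (adjusted p = 0.00413), and ATG3, its conjugating enzyme, from 0.17 to 3.12 (adjusted p = 0.024). ATG17 fell to -1.12 at 8 h (adjusted p = 0.00526), and ATG11 stayed between -0.17 and -0.05. Among 16 genes 8 were induced and 8 met neither rule, with 11 called over all genes and 12 adjusted over the list alone.

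Stress genes split. The heat shock chaperone genes SSA3 and SSA4 rose from -0.08 and -0.05 at 3 h to 2.66 and 2.07 at 5 h (adjusted p = 0.0162 and 0.00916). The trehalose synthesis gene TPS2 fell to -2.28 at 5 h (adjusted p = 0.00404), and the catalase gene CTT1 stood at -2.22 at 3 h and 1.62 at 8 h (adjusted p = 0.0306). Of 15 measured members 4 were induced (SSA3, SSA4, HSP26 and HSP82), 6 were repressed and 5 were in neither class (HSP12, HSP42, HSP78, SSA1 and TPS1). The list median ranged from -0.76 at 3 h to 0.24 at 6 h, and 8 trends were called over all genes and 8 adjusted over the list alone. At 5 h the median of -0.01 becomes 0.01 when the columns are centred.

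Of the 2 lists set out for cycling cells, START genes moved little or in different directions, and all 4 septin genes with a called trend rose. CLN2, a G1 cyclin gene, ranged from -0.40 to 0.21 (adjusted p = 0.26). CLN3 was repressed throughout (-1.40 to -1.21) and was the only repressed member of 8 in the START list, and SWI4, of the G1 transcription factor, was the only induced one (1.77 at 6 h). PCL2 fell from 0.34 to -0.85 (adjusted p = 0.00678) and MBP1 rose from -0.31 to 0.79 (adjusted p = 0.0325). Trends numbered 3 (PCL2, MBP1 and SWI4) over all genes and 3 adjusted over the list alone. Among 5 septin genes, CDC10 and CDC3 rose to 4.84 and 4.76 at 8 h (adjusted p = 0.0131 and 0.0144), SHS1 and CDC11 met neither rule, and CDC12 stayed between -0.52 and -0.27. CDC10 and CDC3 stood at 0.41 and 0.91 at 3 h and at 4.46 and 4.22 at 5 h. The middle sporulation median stepped up over the same hours, so the rise of CDC10 and CDC3 is no measure of cycling cells. The septin calls were 4 (all but CDC12) over all genes and 4 adjusted over the list alone.

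Of 17 measured genes of haploid cells and mating 6 were induced and 11 met neither rule. STE3, a pheromone receptor gene, rose from 0.57 at 1 h to 4.55 at 5 h (adjusted p = 0.00393), and STE4, of the pheromone-responsive G protein, from 0.06 to 3.87 (adjusted p = 0.014). AGA2, STE5, STE18 and FAR1 were the others. STE6 and SST2 fell to -0.76 and -0.56 (adjusted p = 0.0103 and 0.0306), and the pheromone genes MFA2, MF(ALPHA)1 and MF(ALPHA)2 stayed between -0.21 and 0.42. Medians of the list lay between 0.13 and 0.56, with 9 trends over all genes and 9 adjusted over the list alone.

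Genes for methylation of lysine 4 of histone H3 and associated factors had medians between -0.13 and 0.16. SET1, the methyltransferase gene, rose from 0.31 at 1 h to 1.22 at 5 h (adjusted p = 0.031), and SWD1, of the same complex, stood at 0.66 at 4 h and 2.46 at 5 h (adjusted p = 0.0688). JHD2, the demethylase gene, rose from -0.90 to 1.78 at 5 h (adjusted p = 0.014), and BRE2 was the other induced gene (1.75 at 8 h). SWD2 and RTF1 were repressed at -1.22 at 5 h and -1.23 at 4 h. The other 11 of 17 met neither rule, and 8 trends were called over all genes and 8 adjusted over the list alone.

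Of 5 genes used as stable references, ACT1 stayed between -0.41 and 0.14 (adjusted p = 0.231) and TAF10 and TFC1 met neither rule. ALG9 and UBC6 rose to 2.34 and 2.28 at 8 h (adjusted p = 0.0114 and 0.0198). Those 2 were called over all genes and the same number adjusted over the list alone.

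Across all genes the trend test called 2747, 1320 upward and 1427 downward. Which direction had more calls depended on the processing, with 1368 upward and 1320 downward in centred columns and 1280 and 1060 in scaled columns. Without the 8 h column the numbers were 1488 and 1152, but direction is then the fitted value at 6 h minus that at 1 h. A further measure of the overlap with the rules of size is that 986 of the induced and 500 of the repressed genes were called, and 1271 called genes met neither rule. The p-values measure only how far time points scatter around a curve, and the time points come from the same cultures. The median scatter of the time points around the curve was 0.194 on the log2 scale. The measured and fitted difference between 8 h and 1 h had opposite signs in 37 called genes. The count was 1488 without the 2 h column and 1405 without the 6 h column, 4150 with a natural spline and 1459 with an ordinary F test.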

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

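The ratio to 1 h and the restriction to protein-coding rows were tests chosen after the values were seen. All other alternatives were planned. No list median changed sign at its largest hour. At other hours, centring or scaling changed the sign of the stress and heat shock median at 5 h alone (-0.01 as deposited, 0.01 centred), and the mean had the other sign for some medians near 0, such as nitrogen catabolite repression at 8 h (-0.08, mean 0.296) and the divisions at 1 h (-0.06, mean 0.433). The induced count was between 1132 and 1196 and the repressed count between 800 and 910 when each time point was left out in turn, and both stayed within 1.5 times under either scaling of the columns and with runs of 1 or 3 time points. A 1.5-fold threshold gave 1949 induced and 1791 repressed genes, and a 3-fold threshold 676 and 355, as the thresholds' construction implies. Against 1 h in place of 0 h, 1109 genes were induced and 603 were repressed. A fall completed by 1 h does not count against 1 h, and the first run of repression against 0 h began at 1 h for 321 genes. How much of the lower repressed count this makes up was not tested. The trend count lay between 1405 and 2640 with a time point left out (1488 without 2 h), at 4150 with a natural spline and at 1459 with an ordinary F test. Downward calls outnumbered upward ones as deposited. Upward ones were more numerous in centred (1368 against 1320) and scaled columns (1280 against 1060), with the linear term (1153 against 1123) and with the spline (2193 against 1957). They were also more numerous without 5 h (1221 against 1201) and without 8 h (1488 against 1152). Without 8 h, direction is the fitted value at 6 h minus that at 1 h. The cause of these differences was not tested. Leaving out a time point removes 1 of 4 residual degrees of freedom, and the cause of the lower counts without 2 h and 6 h was not tested further. Rows with a partial set of values or a repeated name do not occur, so leaving out such rows changed nothing by construction. No paired analysis was possible because each time point has 1 column and no replicate numbers.

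Scaling the columns to the same spread moved the largest median of the meiotic regulators to 1.36, divisions to 3.18, DNA replication to 1.52, cohesin to 2.05, ribosomal proteins to -3.07, ribosome biogenesis to -2.62, glycolysis to -3.62, gluconeogenesis to 1.29, oxidative phosphorylation to -1.41 and nitrogen catabolite repression to 2.59. The mean in place of the median was 2.13 for meiotic regulators, 2.54 for break formation, 2.84 for strand exchange, 2.01 for cohesin, -4.00 for glycolysis, 0.439 for gluconeogenesis, -0.149 for START, 1.06 for haploid cells and mating and 1.95 for septins.

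The hour of the highest median moved under scaling to 3 h for break formation, axis and synapsis, and autophagy, and to 8 h for the divisions, and under centring to 8 h for autophagy. On the fitted quadratic curve it was 1 h for DNA replication, cohesin and amino acid biosynthesis, 2 h for oxidative phosphorylation, 3 h for the TCA cycle, 4 h for core histones, 5 h for break formation and for axis and synapsis, 6 h for meiotic regulators, strand exchange and reference genes, and 8 h for the divisions, autophagy and septins. That curve put 705 induced genes highest at 8 h, against 432 to 459 with a time point left out. With a time point left out, the hour ranged from 1 to 2 h for DNA replication, glycolysis, gluconeogenesis, nitrogen catabolite repression and amino acid biosynthesis, 1 to 3 h for START, 1 to 4 h for the TCA cycle, 2 to 3 h for core histones and cohesin, 3 to 4 h for break formation and oxidative phosphorylation, 3 to 8 h for ribosomal proteins and ribosome biogenesis, 4 to 5 h for axis and synapsis, strand exchange and the proteasome, 4 to 8 h for autophagy, 5 to 6 h for meiotic regulators, stress, histone H3 methylation, septins and reference genes, and 6 to 8 h for the middle, division, late and haploid lists. For named genes under centring and scaling, 188 values moved by less than the scatter around their curve and 64 by more, and no induced or repressed gene changed sign. Signal over background was not analysed here, so which low genes it limits is unknown.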

Other observations

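The tests of the wider spread at 5 h, and all lists in this part, were chosen after values had been seen. Subunits of the anaphase-promoting complex, the ubiquitin ligase that drives the metaphase to anaphase transition, were induced together with the division genes. Of 11 measured subunits 10 were induced, with a median of 0.53 at 3 h, 1.07 at 4 h and 3.27 at 5 h. CDC27 rose to 5.64 at 8 h (adjusted p = 0.00636) and CDC16 to 3.80 (adjusted p = 0.0171), while DOC1 was highest at 4 h (3.23) and MND2, a meiotic inhibitor of the complex, met neither rule (0.97 at 4 h). Kinetochore genes had a median of at most 0.69, with 10 of 27 induced, among them NDC80 (2.93 at 5 h) and IPL1 (2.84 at 4 h). Of 21 seripauperin genes 14 were induced and 20 were called by the trend test, with a median of 1.54 at 8 h, but these copies are near-identical and their separate values are uncertain. Hexose transporters split, with HXT14 at 9.33 and HXT10 at 7.93 at 8 h and HXT7 and HXT4 at -3.40 and -2.74 at 1 h.

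Ergosterol synthesis genes were lowest late, with 10 of 23 repressed and a median of -0.88 at 6 h. ERG3 stood at -3.29 at 5 h (adjusted p = 0.0281), whereas HMG2 was induced (2.32 at 5 h). Of 62 mitochondrial ribosomal protein genes 33 were repressed and 5 induced (MRP20, MRP49, MRPL27, MRPL37 and MRPS17), of which MRPS17 went from -1.53 at 2 h to 4.19 at 8 h. Vacuolar ATPase genes stayed near 0, with VMA8 the 1 repressed gene of 13. Over all genes and adjusted over the list alone, the trend test called 10 and 10 of the anaphase-promoting complex, 14 and 14 of the kinetochore, 20 and 20 seripauperin, 10 and 10 hexose transporter, 16 and 16 ergosterol, 23 and 22 mitochondrial ribosomal, 7 and 7 vacuolar ATPase and 12 and 12 iron uptake genes.

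Iron uptake is a hypothesis that came from 2 low genes. FIT2 and FET3 stood at -4.25 and -3.76 at 8 h, and a candidate explanation is that iron uptake genes were low as a group. The other 17 measured genes had a median of -1.07 at 5 h, below all 10000 random lists, but it was -1.35 at 4 h and -0.54 at 8 h. At 8 h, the hour of the FIT2 and FET3 values, that is only just below the 2.5th centile of random lists (-0.52). Of the 12 trend calls in the list, 5 were upward and 7 downward. Among them 10 were repressed, including SIT1 (-3.97 at 8 h) and FTR1 (-2.93), but FTH1, FET5 and FRE6, which act at the vacuole, were induced, FTH1 and FET5 at 2.42 and 3.13. No metal level was measured.

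The real order of the time points gave 2747 genes with a trend, and 1 of 100 orders, the real one, gave as many. The highest of the other orders gave 676. Consecutive columns resemble each other, so a smooth curve suits the real order better whatever made the columns change gradually. The comparison therefore cannot tell the source of the count or its error rate.

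The spread of the ratios widened from 4 h to 5 h, from an SD of 1.05 to 1.48. A single scale factor on the later arrays stretches every quantile alike, but the 95th percentile of the centred ratios widened 1.58 times and the 5th percentile 1.28 times. The difference of 0.297 (bootstrap SD over genes 0.0573) argues against it as the whole cause and leaves it open as a part. Below the upper tail the widening was more even. The quartiles went from -0.48 and 0.52 to -0.65 and 0.67, and the median absolute deviation from 0.50 to 0.66. A common factor there is left open. A rise of induced genes alone, with no common factor, is also argued against by the 1.28 of the 5th percentile (bootstrap SD over genes 0.0258). Together with a common factor it is left open, since that factor would widen the 5th percentile as well. Both bootstraps resampled genes within 1 column per hour and do not measure error between arrays or cultures. A first test of the scale factor used the correlation between 4 h and 5 h (0.862), which does not measure spread. It was replaced after its result was seen. Between these hours the middle list median moved by 3.21 and the late list median by 3.60, and that of amino acid biosynthesis by -0.945 and of glycolysis by -0.83. The glycolysis median at 5 h was 1.23 times that at 4 h, within the widening of the 5th percentile. The amino acid biosynthesis median changed sign, from 0.14 to -0.81. No biological explanation was tested.

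Several unannotated reading frames followed an annotated neighbour on the other strand, such as YCR013C with PGK1 (r = 0.999) and YKL153W with GPM1 (r = 0.911), and a candidate explanation is signal shared with that gene. Over 421 pairs with an other-strand neighbour the median r was 0.700, against 0.223 for annotated genes, a difference of 0.477 (bootstrap SD 0.0413) that is in line with it. Regulation of neighbours together, if alike on both strands, is argued against as the whole cause, since same-strand neighbours gave 0.419, lower by 0.281 (bootstrap SD 0.081). Neighbours here are adjacent by the number in the systematic name, and whether a pair overlaps was not examined. Other-strand pairs were not split by orientation, so regulation shared by divergent neighbours was not tested apart and stays open. The same-strand value of 0.419 was itself above the 0.197 of annotated genes with same-strand neighbours, and the cause of this was not tested. A first version of this test took only the best neighbour of each row, which favours rows with more neighbours, and was replaced after its result was seen; its medians were 0.838 and 0.386, with the same outcome.

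Induced genes lay next to each other more often than shuffles gave. Of 5151 neighbouring non-overlapping pairs 351 had both genes induced, against a median of 249 and a highest value of 300 in 10000 shuffles, so a chance arrangement is argued against. A shared region between divergent genes could add to this, but the share of pairs with both induced was 7.27% for divergent, 6.74% for tandem and 6.50% for convergent pairs, and the difference of 0.77 points between divergent and convergent (bootstrap SD 0.956) leaves it open. Signal from overlapping transcript ends was not tested.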
